A study of Gallus gallus with 21 samples.

How the data were processed

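RNA-seq was run on 21 libraries from contour feather follicles of male white leghorn chickens that were 1 year old, as total RNA extracted with TRIzol and made into libraries with a TruSeq RNA kit, per the labels. Experiment 1 had 12 libraries in 4 groups of 3 (dermal papilla, dermal sheath, peripheral pulp and central pulp of early growth follicles). Experiment 2 had 9 libraries, 2 each of pulp in early growth, late growth and near rest and 3 of the resting apical dermal papilla. Groups and replicate numbers were taken from the labels, which do not say whether replicates came from separate birds or whether both experiments used the same birds.

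The authors deposited 1 table per experiment, with values per gene in TPM, a share of all transcripts corrected for transcript length and scaled to one fixed total per library. TopHat2 2.1.1, Cufflinks 2.2.1.2 and Cuffdiff 2.2.1.3 are named, without a role, in the submitters' processing notes. The genome build and the gene annotation are not given in the sources used here, so no coordinates are printed. TPM divides by the library's own total, so a rise in a few abundant genes lowers all others, and it keeps no depth. The precision of weakly expressed genes is therefore unknown, and an exact 0 is reported only as listed at 0. The table of experiment 1 held 13815 genes, each with a mean over its libraries of at least 1.001 TPM. The table of experiment 2 held 23789 genes, of which 4855 were at 0 in all libraries. As the tables were normalized separately, every test was made within 1 table.

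Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a pseudocount of 1, a group-means model over all libraries of the experiment, and moderated variances with trend and robust settings. Genes needed at least 1 TPM in at least 3 libraries (experiment 1) or 2 libraries (experiment 2), which left 13804 and 14915 genes. P-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p under 0.05, two-sided. Residual degrees of freedom were 8 and 5. Each part of experiment 1 was compared with the mean of the other 3, the dermal papilla with the sheath and with the mean of both pulp parts, and peripheral with central pulp. In experiment 2 the stages were compared in pairs, and the resting apical dermal papilla with near resting and with early growth pulp.

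A collection of 32 gene lists for pathways and cell types was fixed before the data were examined, together with the groups, tests and alternatives. Of 954 list entries, 737 were tested in experiment 1 and 757 in experiment 2, with 6 and 7 entries matched through an older symbol. Lists with at least 5 tested genes were compared with all other genes by limma's camera, with a preset correlation of 0.01 and with a correlation estimated from the residuals, adjusted over the lists of each contrast. Camera called 136 of 384 list-by-contrast tests with the preset correlation and 0 with the estimated one. For a list, counts are also given adjusted over the list alone.

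Genes were named by a rule: per contrast, the 8 largest and 8 smallest log2 fold changes among called genes with a symbol, at least 10 TPM on average in the higher group and no overlap between the libraries of the 2 sides, and up to 4 members with the smallest p-value in each list described. A gene listed at 0 in all libraries of a group is named without a fold change against that group. Some genes that the rule takes are not reported here. HBBA, KRT5 and PTPRC were followed in every group as markers of blood, epidermis and leukocytes. Members of multigene families, such as the defensins, ovodefensins, cathelicidins, keratins and genes of the epidermal differentiation complex, can share reads with near-identical copies, so their single values are uncertain.

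The limma step was tested on simulated data with 200 changed genes, all of higher mean expression, and with errors independent between genes. For dermal papilla against sheath (13404 genes) it recovered 70% of 2-fold and 91% of 4-fold changes, and 4.17% of its calls were false. For near resting against late growth pulp (13600 genes) it recovered 56% and 89%, and 7.05% of its calls were false. In the real data 37.7% and 31.1% of genes were called in these contrasts, so the simulated shares need not carry over. Replicate libraries were compared before use: the SD of their log2 difference lay between 0.32 and 0.64, and no pair was near-identical. The alternatives tried were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, no trend or robust variance, the replicate number as a block, a fit on only the groups compared, 50 in place of 200 genes per set followed across experiments, and leaving out each library in turn.

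Values in the tables whose gene name was a spreadsheet date number (16 and 21) or occurred more than once (14 and 47) were not described. Genes named by an Ensembl identifier (3267 and 10668) were tested and counted but not named.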

Results

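RNA was sequenced from parts of the adult contour feather follicle of 1 year old male white leghorn chickens. A follicle makes a new feather in each cycle: the dermal papilla at its base is surrounded by the dermal sheath, and during growth the mesenchymal pulp fills the feather shaft and is resorbed as the follicle nears rest. Experiment 1 held 12 libraries of the early growth follicle, 3 each of dermal papilla, dermal sheath, peripheral pulp and central pulp. Experiment 2 held 9 libraries, 2 each of pulp in early growth, late growth and near rest, and 3 of the apical dermal papilla at rest. Values are TPM, a transcript share scaled to one fixed total per library, given as mean ± SD over the libraries of a group (n = 3 in experiment 1 and for the resting apical dermal papilla, n = 2 for each pulp stage). The sequencing depth of the libraries is unknown, because TPM keeps no depth. Between 12569 and 13451 genes reached 1 TPM in a library. The labels do not say that replicates came from separate birds, so p-values measure only the spread between these samples, which may be technical. Fold changes are on the log2(TPM + 1) scale, which understates the change of weakly expressed genes, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

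The first question was which genes distinguish the 4 dermal parts of the early growth follicle. Expression of 10532 of 13804 genes differed between the parts in the limma F test at an adjusted p under 0.05. TAGLN, an actin-binding protein of smooth muscle, was at 9280.3 ± 1032 TPM in the dermal papilla, 4237 ± 603 TPM in the sheath, 22.7 ± 9.59 TPM in peripheral pulp and 172 ± 81.8 TPM in central pulp. ASIP, the agouti signalling protein that antagonises melanocortin receptors, was at 3381 ± 859 TPM in peripheral pulp and 2879 ± 1323 TPM in central pulp, against 14.1 ± 1.77 TPM in the dermal papilla and 0.025 ± 0.033 TPM in the sheath.

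**Figure D1:**
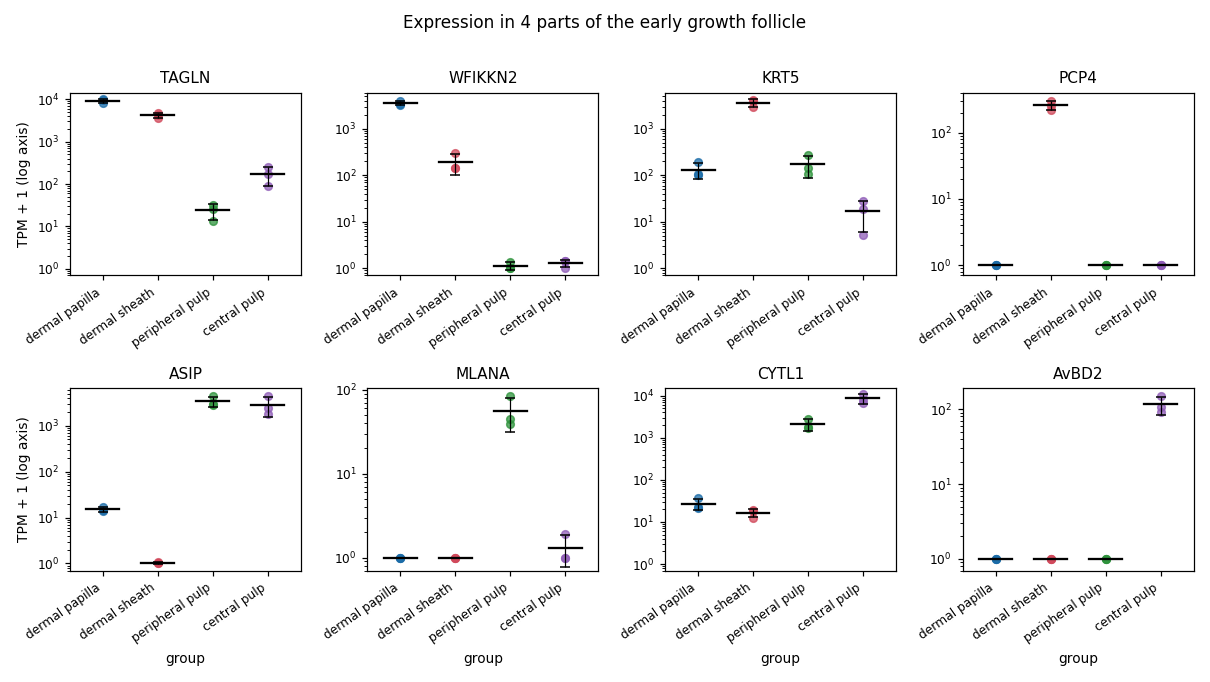
TPM + 1 on a log axis for 8 genes in each library of experiment 1 (points), with the mean (line) and SD (bars) of the 3 libraries of each follicle part. TAGLN is high in dermal papilla and sheath, ASIP and CYTL1 in both pulp parts, and PCP4, MLANA and AvBD2 each stand high in 1 part.

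The dermal papilla was compared with the mean of the other 3 parts. The largest increase among the named genes was in WFIKKN2, which encodes a secreted protein that binds myostatin and GDF11, at 3547 ± 350.2 TPM against 196 ± 95.5 TPM in the sheath and under 1 TPM in both pulp parts (log2 fold change of 9.12 ± 0.22 (SE), adjusted p = 4.5e-10). The smooth muscle genes ACTG2, MYH11 and TAGLN and the skeletal muscle actin ACTA1 were higher, with log2 fold changes of 6.07 ± 0.32, 5.36 ± 0.22, 5.23 ± 0.31 and 5.90 ± 0.21 (SE). TMEM255B (433 ± 37.0 TPM), the small heat-shock gene HSPB7 (492 ± 7.05 TPM) and SHISAL1 (56.6 ± 16.7 TPM) were also among the genes with the largest increases. Lower in the papilla than in every other part were PTHLH, the parathyroid hormone-related peptide, at 3.51 ± 0.517 TPM (log2 fold change of -4.67 ± 0.11 (SE), adjusted p = 2.4e-10), the chemokine CXCL14 (-4.43 ± 0.38), WNT11 (-4.41 ± 0.13) and the hedgehog-binding HHIP (-4.39 ± 0.16). The vitamin A enzyme gene CYP27C1, COL13A1 and ATP6V1G3 were lower by the same test.

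Of the smooth muscle contractile list, 20 of 20 were higher, 0 lower and 0 not called (20 and 0 adjusted over the list alone). Smooth muscle genes had a median log2 fold change of 3.09 (camera adjusted p = 5.3e-17, adjusted p = 0.12 with an estimated correlation). ACTA2 was at 4068 ± 526 TPM in the papilla and MYLK, the myosin light chain kinase, at 431 ± 19.9 TPM. Of the cell cycle list, 0 of 38 were higher, 38 lower and 0 not called (0 and 38 adjusted over the list alone). Cell cycle genes had a median log2 fold change of -1.53 (camera adjusted p = 1.4e-16, adjusted p = 0.13 with an estimated correlation). The cytokinesis gene ANLN was at 5.34 ± 0.765 TPM in the papilla against 62.0 ± 5.83 TPM in peripheral pulp. Of the leukocyte list, 1 of 22 were higher, 20 lower and 1 not called (1 and 20 adjusted over the list alone). Leukocyte genes had a median log2 fold change of -1.77 (camera adjusted p = 1.8e-09, adjusted p = 0.11 with an estimated correlation). C1QA, a complement gene of macrophages, was at 39.7 ± 1.54 TPM against 239.9 ± 13.3 TPM in central pulp. Of the BMP pathway list, 17 of 31 were higher, 6 lower and 8 not called (17 and 6 adjusted over the list alone). BMP pathway genes had a median log2 fold change of 0.50 (camera adjusted p = 0.0016, adjusted p = 0.11 with an estimated correlation). BMP4 (2.51 ± 0.15), BMP7 (2.27 ± 0.11) and the antagonist CHRDL1 (4.38 ± 0.13) rose together, and the antagonist NOG was at 18.5 ± 3.25 TPM in the papilla and listed at 0 in central pulp. In all, 7333 of 13804 genes passed, 3186 higher and 4147 lower, of which 991 and 1525 changed at least 2-fold. After quantile normalization 3456 were higher and 3594 lower.

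The dermal sheath was compared with the other 3 parts in the same way. PCP4, a calmodulin-binding protein gene, was at 257 ± 40.7 TPM in the sheath and listed at 0 in all 9 other libraries of the experiment. APOA1 (2650.2 ± 328 TPM), the tendon gene TNMD (1427 ± 124 TPM), the cartilage matrix gene CILP2 (415 ± 45.0 TPM), FABP4 (389.8 ± 29.2 TPM), COL28A1 (184 ± 3.39 TPM) and the complement gene C7 (151 ± 10.8 TPM) were highest there, with log2 fold changes (SE) from 5.30 ± 0.17 for C7 to 6.10 ± 0.22 for APOA1. Among the largest decreases were those of ASIP (log2 fold change of -8.96 ± 0.22 (SE), adjusted p = 2.2e-10), the growth factor PTN at 6.13 ± 5.50 TPM against 701 ± 83.6 TPM in the papilla and 462 ± 78.4 and 1718 ± 205 TPM in peripheral and central pulp, COL26A1 (-6.96 ± 0.40), PHEX (-6.25 ± 0.29), TFAP2C (-6.20 ± 0.14) and FBN2 (-5.90 ± 0.14).

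Lists for other cell types went both ways in the sheath. Of the epidermal keratinocyte list, 17 of 22 were higher, 3 lower and 2 not called (17 and 3 adjusted over the list alone). Keratinocyte genes had a median log2 fold change of 3.26 (camera adjusted p = 3.1e-06, adjusted p = 0.33 with an estimated correlation). The basal keratins KRT5 and KRT14 stood at 3651 ± 639 and 2231 ± 516 TPM in the sheath, and KRT5 was at 132 ± 50.2 TPM in the papilla. Of the erythroid list, 8 of 9 were higher, 1 lower and 0 not called (8 and 1 adjusted over the list alone). Erythroid genes had a median log2 fold change of 1.29 (camera adjusted p = 0.0023, adjusted p = 0.33 with an estimated correlation). Hemoglobin HBA1 was at 2617 ± 157 TPM. Of the smooth muscle list, 19 of 20 were higher, 1 lower and 0 not called (19 and 1 adjusted over the list alone). For smooth muscle genes the median log2 fold change was 2.38 (camera adjusted p = 2.4e-12, adjusted p = 0.32 with an estimated correlation). DES, the muscle intermediate filament gene, was at 4462 ± 794 TPM. Of the Schwann cell and nerve list, 13 of 16 were higher, 2 lower and 1 not called (13 and 2 adjusted over the list alone). Schwann cell and nerve genes had a median log2 fold change of 1.25 (camera adjusted p = 1.3e-04, adjusted p = 0.10 with an estimated correlation). The neurofilament gene NEFL (2.44 ± 0.24) and the neurotrophin receptor NGFR (2.29 ± 0.26) were higher. Of the endothelial list, 9 of 14 were higher, 0 lower and 5 not called (9 and 0 adjusted over the list alone). Endothelial genes had a median log2 fold change of 0.49 (camera adjusted p = 2.7e-04, adjusted p = 0.33 with an estimated correlation). Among its smallest p-values were those of the lymphatic marker LYVE1 (3.84 ± 0.18) and MMRN1 (4.92 ± 0.39). Of the adipocyte list, 7 of 18 were higher, 2 lower and 9 not called (7 and 2 adjusted over the list alone). For adipocyte genes the median log2 fold change was 0.33 (camera adjusted p = 0.0078, adjusted p = 0.19 with an estimated correlation). Of the cartilage and bone list, 7 of 14 were higher, 4 lower and 3 not called (8 and 4 adjusted over the list alone). Cartilage and bone genes had a median log2 fold change of 0.64 (camera adjusted p = 0.026, adjusted p = 0.33 with an estimated correlation). Its camera adjusted p was 0.074 with median-of-ratios scaling and 0.061 after quantile normalization. Of the pericyte and mural cell list, 2 of 8 were higher, 2 lower and 4 not called (2 and 2 adjusted over the list alone). Pericyte and mural cell genes had a median log2 fold change of 0.03 (camera adjusted p = 0.52, adjusted p = 0.76 with an estimated correlation). Of the leukocyte list, 1 of 22 were higher, 16 lower and 5 not called (1 and 16 adjusted over the list alone). For leukocyte genes the median log2 fold change was -0.91 (camera adjusted p = 0.0026, adjusted p = 0.33 with an estimated correlation). Of the melanocyte list, 1 of 8 were higher, 6 lower and 1 not called (1 and 6 adjusted over the list alone). Melanocyte genes had a median log2 fold change of -1.53 (camera adjusted p = 0.12, adjusted p = 0.49 with an estimated correlation). The test called 2731 genes higher and 4928 lower. With median-of-ratios scaling, which moved the median of all genes by 0.12, the split was 3633 to 3810, and after quantile normalization it was 3345 to 4052.

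**Figure D2:**
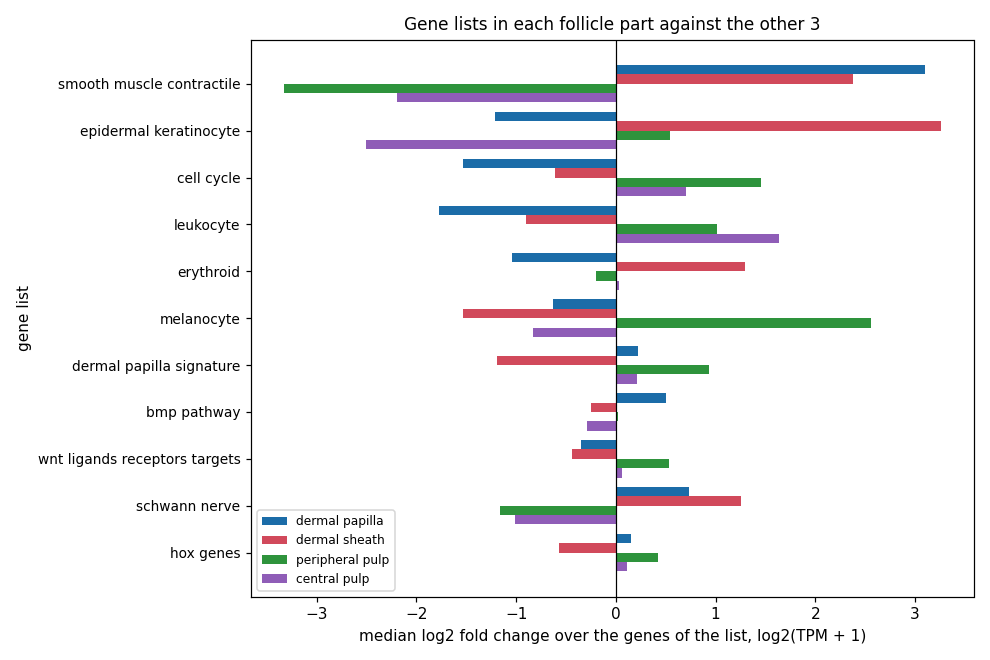
Median log2 fold change over the measured genes of 11 gene lists (bars), for each part of the early growth follicle against the mean of the other 3 parts. Smooth muscle genes are higher in dermal papilla and sheath and lower in both pulp parts, while cell cycle and leukocyte genes run the other way.

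In peripheral pulp the axon guidance gene DRAXIN was at 737 ± 109 TPM, against 432 ± 65.6 TPM in central pulp and 2.46 ± 0.598 TPM in the papilla (log2 fold change of 5.34 ± 0.13 (SE), adjusted p = 4.3e-10). Somatostatin (SST, 456 ± 233 TPM), ISLR2 (604 ± 43.7 TPM), the retinoid-binding CRABP-I (85.0 ± 63.4 TPM) and KCNIP2 (99.0 ± 29.0 TPM) were also higher there than in all other libraries. The melanosome gene MLANA was at 54.7 ± 24.2 TPM, and was listed at 0 in the dermal papilla and sheath. Among the largest decreases were those of the contractile genes ACTG2 (-7.72 ± 0.32), DES (-7.41 ± 0.22), MYH11 (-6.58 ± 0.22) and CNN1 (-5.75 ± 0.26), and of OSTN, a muscle and bone peptide that binds the natriuretic peptide clearance receptor (-6.28 ± 0.12).

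Of the cell cycle list in peripheral pulp, 38 of 38 were higher, 0 lower and 0 not called (38 and 0 adjusted over the list alone). For cell cycle genes the median log2 fold change was 1.45 (camera adjusted p = 2.2e-14, adjusted p = 0.26 with an estimated correlation). ANLN (2.34 ± 0.09), NUF2 (1.71 ± 0.09), CCNB2 (1.34 ± 0.07) and RRM1 (1.11 ± 0.06) had the smallest p-values. Of the Wnt ligand, receptor and target list, 18 of 35 were higher, 3 lower and 14 not called (18 and 3 adjusted over the list alone). Wnt genes had a median log2 fold change of 0.53 (camera adjusted p = 0.0024, adjusted p = 0.26 with an estimated correlation). With a pseudocount of 0.1 the median was 0.93. WNT11 was at 689 ± 162 TPM, LEF1 at 97.2 ± 16.8 TPM and NOTUM, a secreted Wnt deacylase, at 209 ± 56.5 TPM. Of the leukocyte list, 15 of 22 were higher, 1 lower and 6 not called (15 and 1 adjusted over the list alone). Leukocyte genes had a median log2 fold change of 1.01 (camera adjusted p = 0.0012, adjusted p = 0.38 with an estimated correlation). LAPTM5 rose (1.21 ± 0.07), whereas the macrophage mannose receptor MRC1 fell (-3.40 ± 0.20). The test called 4860 genes higher and 2531 lower in peripheral pulp. With median-of-ratios scaling the median of all genes moved by -0.14 and the split became 3300 to 3398, and with quantile normalization it was 3635 to 3290.

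In central pulp the chemokine CXCL14 was at 9272 ± 1500.0 TPM, the cytokine-like CYTL1 at 8639 ± 2126 TPM (log2 fold change of 6.46 ± 0.22 (SE), adjusted p = 3.8e-09) and the cell surface protein gene PSCA at 413 ± 89.5 TPM. LECT2, a chemotactic protein gene, was at 211 ± 53.2 TPM, the defensins AvBD2 and BD7 at 115 ± 30.8 and 73.6 ± 19.1 TPM, the cathelicidins CATHL3 and CATHL2 at 61.2 ± 9.62 and 51.3 ± 13.4 TPM, and the calcium-binding S100A9 at 61.4 ± 39.7 TPM. LECT2, the 2 defensins and the 2 cathelicidins were listed at 0 in the dermal papilla and sheath, and AvBD2, CATHL2 and CATHL3 also in peripheral pulp. Lower in central pulp than elsewhere were KAZALD1 (-5.66 ± 0.20), CHRDL1 (-5.40 ± 0.13), FGF10 (-4.89 ± 0.27), FMOD (-4.85 ± 0.31) and C1QTNF12 (-5.01 ± 0.22).

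Of the leukocyte list in central pulp, 20 of 22 were higher, 1 lower and 1 not called (20 and 1 adjusted over the list alone). For leukocyte genes the median log2 fold change was 1.63 (camera adjusted p = 2.8e-10, adjusted p = 0.084 with an estimated correlation). LY86, a partner of an innate immune receptor, was at 506 ± 118 TPM and LCP1, an actin-bundling protein of leukocytes, at 85.2 ± 1.73 TPM. Among cell cycle genes, 31 of 38 were higher, 0 lower and 7 not called (33 and 0 adjusted over the list alone). Cell cycle genes had a median log2 fold change of 0.70 (camera adjusted p = 2.6e-08, adjusted p = 0.48 with an estimated correlation). AURKA (1.13 ± 0.12) and CCNB2 (0.89 ± 0.07) were among those that rose. Of the glycolysis and hypoxia list, 0 of 21 were higher, 11 lower and 10 not called (0 and 12 adjusted over the list alone). Glycolysis and hypoxia genes had a median log2 fold change of -0.39 (camera adjusted p = 1.8e-04, adjusted p = 0.059 with an estimated correlation). ALDOC (-1.45 ± 0.08), GPI (-0.79 ± 0.07) and TPI1 (-0.64 ± 0.06) fell. Of the inflammation and cytokine list, 9 of 13 were higher, 1 lower and 3 not called (9 and 1 adjusted over the list alone). Inflammation and cytokine genes had a median log2 fold change of 0.62 (camera adjusted p = 0.0090, adjusted p = 0.13 with an estimated correlation). The lymphoid chemokine CCL19 was at 26.8 ± 6.88 TPM. The limma test called 6760 genes, 3588 higher and 3172 lower.

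The dermal papilla and dermal sheath, both rich in smooth muscle transcripts, were then compared directly. PTN was higher in the papilla (log2 fold change of 7.19 ± 0.69 (SE), adjusted p = 3.9e-05), as were the receptor gene PRLHR2 (5.50 ± 0.43), the lens crystallin CRYBB2 (4.95 ± 0.30), NDP, a secreted ligand of frizzled-4 (4.70 ± 0.78), the Wnt inhibitor DKK1 (4.43 ± 0.39) and the histamine methyltransferase HNMT (4.36 ± 0.27). Higher in the sheath were epidermal genes, namely KRT5 (-4.83 ± 0.57), KRT6A (-4.81 ± 0.84), KRT15 (-4.79 ± 0.27), SFN (-4.56 ± 0.60), EDQM3 of the epidermal differentiation complex (-4.74 ± 0.68), GJB6 (-4.86 ± 0.30) and the fatty acid elongase ELOVL4 (-4.63 ± 0.25). PCP4 was listed at 0 in the papilla.

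Of the dermal papilla signature list, 16 of 26 were higher, 2 lower and 8 not called (16 and 2 adjusted over the list alone) in papilla against sheath. Dermal papilla signature genes had a median log2 fold change of 1.08 (camera adjusted p = 1.3e-04, adjusted p = 0.18 with an estimated correlation). The transcription factors TBX18 (2.59 ± 0.12) and ALX4 (2.60 ± 0.22) and the growth factor FGF7 (1.41 ± 0.12, 871 ± 51.5 against 328 ± 5.25 TPM) were higher in the papilla. Of the HOX list, 16 of 27 were higher, 0 lower and 11 not called (17 and 0 adjusted over the list alone). HOX genes had a median log2 fold change of 0.56 (camera adjusted p = 1.0e-04, adjusted p = 0.20 with an estimated correlation). Among its smallest p-values were those of HOXA10 (30.2 ± 1.06 TPM in the papilla and 6.48 ± 2.02 TPM in the sheath) and HOXC10 (1.66 ± 0.14). Of the ribosomal protein list, 1 of 54 were higher, 53 lower and 0 not called (1 and 53 adjusted over the list alone). Ribosomal protein genes had a median log2 fold change of -0.46 (camera adjusted p = 2.0e-21, adjusted p = 0.20 with an estimated correlation). Of the keratinocyte list, 2 of 22 were higher, 16 lower and 4 not called (2 and 16 adjusted over the list alone). For keratinocyte genes the median log2 fold change was -3.44 (camera adjusted p = 6.7e-08, adjusted p = 0.25 with an estimated correlation). EDAR, the ectodysplasin receptor, was one of those higher in the papilla, at 191 ± 22.1 TPM in the papilla and 38.7 ± 14.3 TPM in the sheath. In this comparison 5203 genes passed, 2998 higher in the papilla and 2205 higher in the sheath, against 2533 and 2532 with median-of-ratios scaling.

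Against the mean of both pulp parts, the dermal papilla had 3298 genes higher and 4811 lower, with 3879 and 4192 after median-of-ratios scaling and 3870 and 4131 after quantile normalization. WFIKKN2 (log2 fold change of 11.55 ± 0.24 (SE), adjusted p = 3.0e-11), OSTN (9.53 ± 0.12), ACTA1 (8.52 ± 0.22), DES (8.40 ± 0.23) and CNN1 (7.85 ± 0.28) were higher in the papilla. On the pulp side were ASIP (-7.64 ± 0.23), DRAXIN (-7.36 ± 0.13), CYTL1 (-7.30 ± 0.23), ISLR2 (-6.92 ± 0.17), GCH1, an enzyme gene of tetrahydrobiopterin synthesis (-6.61 ± 0.17), and the ovodefensin genes OvoDA3 at 447 ± 165 TPM and OvoDA1 at 276 ± 107 TPM in peripheral pulp, the last listed at 0 in the papilla. CORIN, a serine protease, was listed at 0 in the papilla and stood at 130.5 ± 28.2 TPM in central pulp.

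More growth factor genes were higher than lower in the papilla. Of the FGF, HGF, IGF and PDGF list, 17 of 35 were higher, 8 lower and 10 not called (18 and 9 adjusted over the list alone). FGF, HGF, IGF and PDGF genes had a median log2 fold change of 0.40 (camera adjusted p = 0.019, adjusted p = 0.48 with an estimated correlation). That median was 0.70 with a pseudocount of 0.1, 0.69 with a filter at 5 TPM and 0.65 after quantile normalization. FGF10 was at 337 ± 83.1 TPM in the papilla against 4.16 ± 0.461 TPM in peripheral pulp (log2 fold change of 6.63 ± 0.28 (SE), adjusted p = 5.8e-09), and PDGFC (2.51 ± 0.10) and IGFBP7 (2.54 ± 0.12) were also higher. Of the BMP pathway list, 17 of 31 were higher, 7 lower and 7 not called (18 and 7 adjusted over the list alone). For BMP pathway genes the median log2 fold change was 0.38 (camera adjusted p = 0.012, adjusted p = 0.097 with an estimated correlation). Among cell cycle genes, 0 of 38 were higher, 38 lower and 0 not called (0 and 38 adjusted over the list alone). For cell cycle genes the median log2 fold change was -1.98 (camera adjusted p = 7.8e-15, adjusted p = 0.16 with an estimated correlation). Of the smooth muscle list, 20 of 20 were higher, 0 lower and 0 not called (20 and 0 adjusted over the list alone). Smooth muscle genes had a median log2 fold change of 4.16 (camera adjusted p = 7.2e-17, adjusted p = 0.097 with an estimated correlation). LMOD1 was at 318 ± 28.6 TPM against 12.0 ± 1.37 TPM in central pulp. Quantile normalization moved the median of all genes by 0.10 in this contrast.

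Peripheral and central pulp differed in 3472 genes, 2159 higher in the peripheral part and 1313 higher in the central part. Higher in the peripheral part were MLANA (log2 fold change of 5.41 ± 0.31 (SE), adjusted p = 8.4e-07), NOTUM (4.34 ± 0.18), the matrix genes HAPLN1 (4.98 ± 0.51) and MATN4 (4.75 ± 0.29), and EDIL3 (4.34 ± 0.62). PRLH, a neuropeptide precursor, was at 35.8 ± 9.89 TPM and listed at 0 in central pulp. LECT2 (log2 fold change of -7.16 ± 0.27 (SE), adjusted p = 2.4e-08), BD7 (-6.00 ± 0.23), S100A9 (-5.68 ± 0.60) and AvBD1 (-5.13 ± 0.26) were higher in central pulp, and CATHL1, at 33.3 ± 8.19 TPM there, was listed at 0 in peripheral pulp.

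More Wnt genes were higher than lower in peripheral pulp. Of the Wnt ligand, receptor and target list, 15 of 35 were higher, 5 lower and 15 not called (17 and 6 adjusted over the list alone) in peripheral pulp. For Wnt genes the median log2 fold change was 0.48 (camera adjusted p = 0.0083, adjusted p = 0.30 with an estimated correlation). LGR5 was at 138 ± 17.2 TPM against 18.2 ± 7.30 TPM in central pulp, and AXIN2 at 149.8 ± 17.2 against 63.7 ± 8.19 TPM. The matrix protease gene MMP27 was also higher in the peripheral part (3.79 ± 0.18). Of the melanocyte list, 5 of 8 were higher, 1 lower and 2 not called (6 and 1 adjusted over the list alone). For melanocyte genes the median log2 fold change was 2.17 (camera adjusted p = 0.0087, adjusted p = 0.35 with an estimated correlation). The median was 1.11 without peripheral pulp replicate 2, with 3 higher and 1 lower, and 3.69 with a pseudocount of 0.1. PMEL and TYRP1 stood at 34.4 ± 22.2 and 21.7 ± 13.1 TPM in peripheral pulp, and the camera adjusted p of this list was 0.22, 0.31 and 0.19 without peripheral pulp replicates 1, 2 and 3 in turn, and 0.085 with a filter at 5 TPM. Of the keratinocyte list, 14 of 22 were higher, 1 lower and 7 not called (16 and 1 adjusted over the list alone). Keratinocyte genes had a median log2 fold change of 2.17 (camera adjusted p = 3.7e-05, adjusted p = 0.35 with an estimated correlation). Without peripheral pulp replicate 1 the median was 1.28. SHH, a ligand made by feather epithelium, was at 42.6, 9.85 and 12.0 TPM in the 3 peripheral libraries. Of the leukocyte list, 0 of 22 were higher, 13 lower and 9 not called (0 and 17 adjusted over the list alone). Leukocyte genes had a median log2 fold change of -0.50 (camera adjusted p = 2.9e-08, adjusted p = 0.11 with an estimated correlation). Of the smooth muscle list, 1 of 20 were higher, 13 lower and 6 not called (1 and 14 adjusted over the list alone). For smooth muscle genes the median log2 fold change was -0.82 (camera adjusted p = 1.8e-08, adjusted p = 0.30 with an estimated correlation). The pericyte gene RGS5 was at 389.6 ± 19.0 TPM in central and 83.3 ± 23.6 TPM in peripheral pulp (-2.25 ± 0.15). Median-of-ratios scaling turned the split of calls to 1368 higher and 1817 lower, and quantile normalization gave 1602 and 1747.

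Experiment 2 followed the pulp from early growth to near rest and set it beside the resting apical dermal papilla. Its table was normalized separately, so no test crosses between the experiments. Between its 4 groups, 12672 of 14915 genes differed in the limma F test. TOP2A, the DNA topoisomerase of dividing cells, fell from 81.5 ± 6.66 TPM in early growth pulp to 16.4 ± 3.20 TPM in late growth, and was at 10.5 ± 1.03 TPM near rest and 2.68 ± 1.02 TPM in the resting papilla. TOP2A was chosen for this description after its values were seen.

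**Figure D3:**
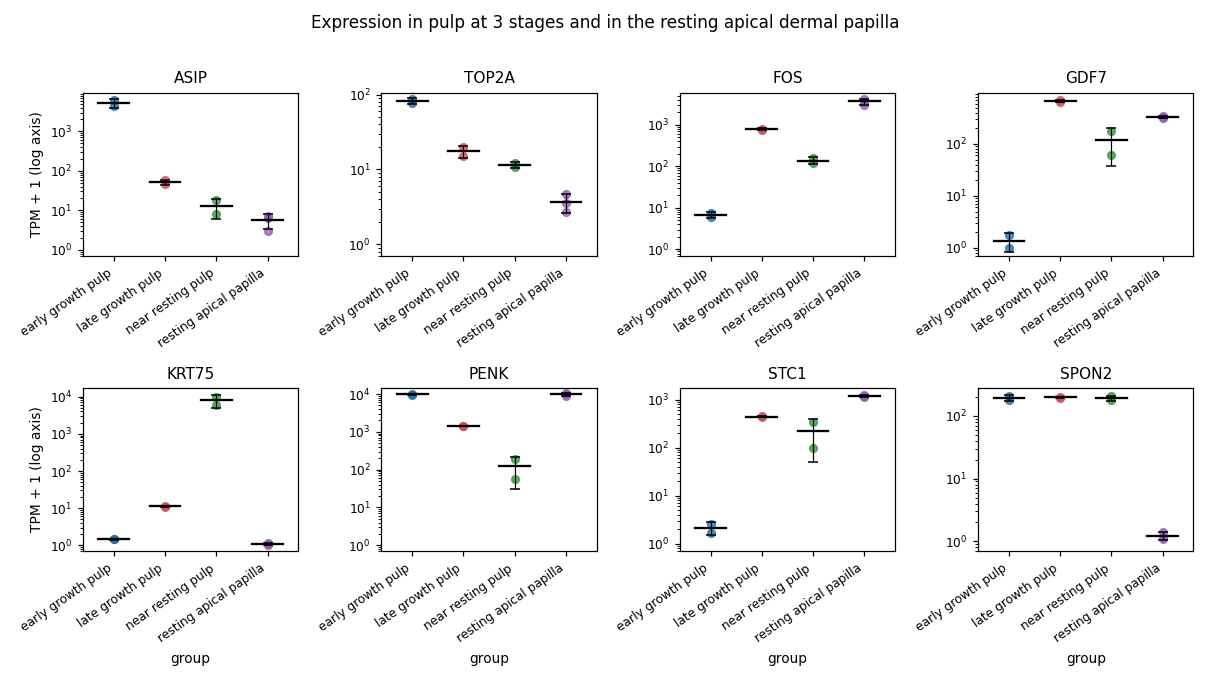
TPM + 1 on a log axis for 8 genes in each library of experiment 2 (points), with the mean (line) and SD (bars) of each group, 2 libraries for each pulp stage and 3 for the resting apical dermal papilla. ASIP and TOP2A are highest in early growth pulp, KRT75 near rest, and FOS and STC1 in the resting apical dermal papilla.

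Between early and late growth, ASIP fell from 5216 ± 1302 to 51.1 ± 7.58 TPM (log2 fold change of -6.63 ± 0.49 (SE), adjusted p = 2.7e-05), and IL17REL (-8.34 ± 0.34), COL14A1 (-7.67 ± 0.29), the water channel AQP5 (-6.91 ± 0.20), the neuropeptide galanin (GAL, -6.73 ± 0.19), CNTN1 (-6.69 ± 0.22) and UCH-L1 (-6.86 ± 0.26) fell with it. GDF7, a BMP family ligand, rose from 0.380 ± 0.537 to 667 ± 26.5 TPM (log2 fold change of 8.98 ± 0.45 (SE), adjusted p = 4.0e-06), as did SMOC2 (8.03 ± 0.37), the hormone stanniocalcin-1 (STC1, 7.74 ± 0.48), CHRDL1 (7.55 ± 0.42) and the heparan sulfate editing enzyme SULF1 (7.20 ± 0.28).

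In late against early growth, of the cell cycle list 0 of 38 were higher, 38 lower and 0 not called (0 and 38 adjusted over the list alone). Cell cycle genes had a median log2 fold change of -2.13 (camera adjusted p = 3.2e-11, adjusted p = 0.27 with an estimated correlation). PLK1 fell from 54.6 ± 6.64 to 5.67 ± 0.403 TPM. Of the immediate-early and stress list, 23 of 24 were higher, 0 lower and 1 not called (23 and 0 adjusted over the list alone). Immediate-early and stress genes had a median log2 fold change of 2.89 (camera adjusted p = 3.0e-14, adjusted p = 0.15 with an estimated correlation). FOS rose from 5.88 ± 1.02 to 782 ± 38.9 TPM (log2 fold change of 6.84 ± 0.19 (SE), adjusted p = 4.0e-07), EGR1 from 38.3 ± 3.98 to 845 ± 22.4 TPM and the chaperone HSP90AA1 from 346 ± 27.9 to 2893 ± 90.8 TPM. Of the BMP pathway list, 18 of 32 were higher, 6 lower and 8 not called (18 and 7 adjusted over the list alone). BMP pathway genes had a median log2 fold change of 0.83 (camera adjusted p = 0.0016, adjusted p = 0.27 with an estimated correlation). BMP4 rose (3.20 ± 0.16) and the BMP antagonist GREM1 fell from 326 ± 30.4 to 15.5 ± 1.23 TPM (-4.31 ± 0.14). Of the endothelial list, 11 of 14 were higher, 0 lower and 3 not called (11 and 0 adjusted over the list alone). For endothelial genes the median log2 fold change was 0.87 (camera adjusted p = 6.1e-05, adjusted p = 0.30 with an estimated correlation). VWF was at 62.5 ± 3.58 TPM early and 211 ± 4.60 TPM late. Of the matrix protease list, 15 of 28 were higher, 4 lower and 9 not called (15 and 5 adjusted over the list alone). Matrix protease genes had a median log2 fold change of 0.73 (camera adjusted p = 0.0030, adjusted p = 0.26 with an estimated correlation). MMP11 (3.71 ± 0.10), MMP9 (5.62 ± 0.30) and the cathepsin CTSK (1.41 ± 0.08) rose. The limma test called 3347 genes higher and 4599 lower in late growth, 1750 and 2296 of them by at least 2-fold. The split was 3922 to 4118 after median-of-ratios scaling and 3859 to 4285 after quantile normalization.

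From late growth to near rest, most genes of the keratinocyte list rose in the pulp libraries. The keratin KRT75 rose from 10.3 ± 0.366 to 7899.7 ± 2950.0 TPM (log2 fold change of 9.40 ± 0.23 (SE), adjusted p = 9.9e-07), EDQM3 from 25.6 ± 1.51 to 4604 ± 148 TPM, ELOVL4 to 380.2 ± 12.1 TPM and the gap junction gene GJB6 to 138 ± 5.72 TPM, while EDCH3, of the epidermal differentiation complex, was at 81.6 ± 1.91 TPM and listed at 0 in late growth. Of the keratinocyte list, 17 of 23 were higher, 1 lower and 5 not called (18 and 1 adjusted over the list alone). For keratinocyte genes the median log2 fold change was 3.73 (camera adjusted p = 1.3e-12, adjusted p = 0.41 with an estimated correlation). The 2 near resting libraries differed in keratins: KRT5 was at 2269 TPM in replicate 1 and 406 TPM in replicate 2, and KRT75 at 9985 and 5814 TPM. SEs and p-values of near resting contrasts use a spread estimate shared by all groups. They therefore do not reflect in full the wider spread between these 2 libraries. SULF1 (log2 fold change of -5.52 ± 0.28 (SE), adjusted p = 1.3e-05), COL9A3 (-5.20 ± 0.67), CILP2 (-4.26 ± 0.17), the natriuretic peptide clearance receptor NPR3 (-4.26 ± 0.54), the neurotrophin receptor NTRK3 (-4.12 ± 0.25) and NR4A3 (-4.19 ± 0.59) fell.

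Endothelial and most smooth muscle genes fell over the same step. Of the endothelial list, 0 of 14 were higher, 14 lower and 0 not called (0 and 14 adjusted over the list alone). Endothelial genes had a median log2 fold change of -1.06 (camera adjusted p = 9.9e-06, adjusted p = 0.41 with an estimated correlation). EGFL7 went from 116 ± 0.861 to 52.8 ± 1.66 TPM. Of the smooth muscle list, 0 of 20 were higher, 14 lower and 6 not called (0 and 15 adjusted over the list alone). Smooth muscle genes had a median log2 fold change of -1.31 (camera adjusted p = 9.5e-06, adjusted p = 0.10 with an estimated correlation). DES went from 60.9 ± 1.98 to 5.53 ± 0.188 TPM. Of the immediate-early and stress list, 0 of 24 were higher, 18 lower and 6 not called (0 and 20 adjusted over the list alone). For immediate-early and stress genes the median log2 fold change was -1.12 (camera adjusted p = 4.1e-06, adjusted p = 0.31 with an estimated correlation). CYR61 (-2.70 ± 0.12) and EGR1 (-2.47 ± 0.12) fell. The limma test called 4641 genes, 1308 higher and 3333 lower near rest. Without late growth replicate 1 it called 857 higher and 1925 lower, and without late growth replicate 2 it called 976 and 1937. The counts were 1084 and 4188 without near resting replicate 1, 2171 and 3288 without near resting replicate 2, and 624 and 1356 when only these 4 libraries were fitted. Median-of-ratios scaling moved the median of all genes by 0.16 and gave 2058 higher and 2025 lower calls, and quantile normalization gave 1724 and 2295.

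**Figure D4:**
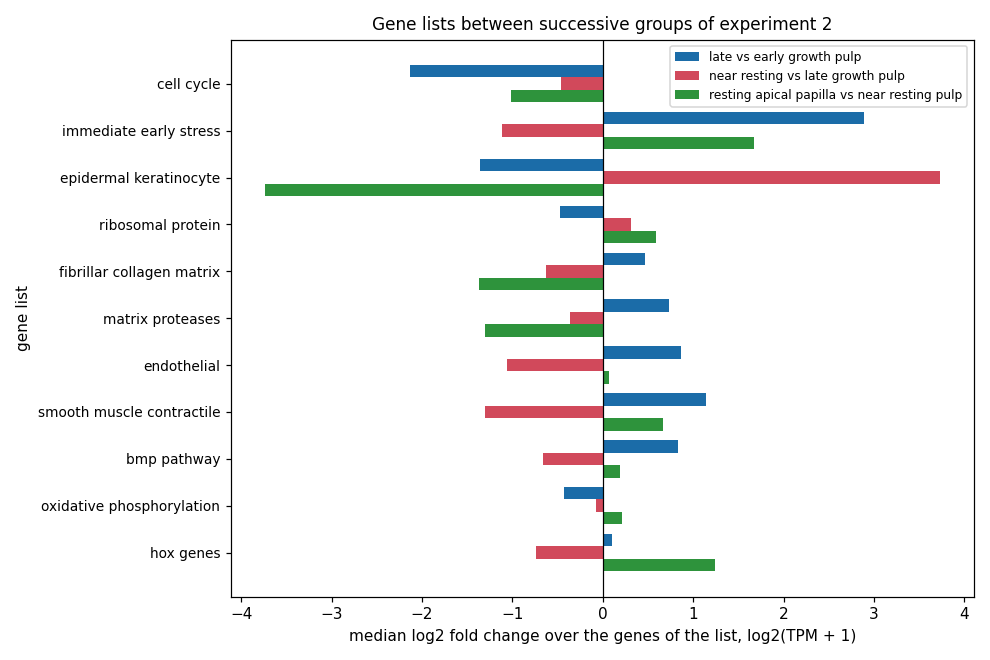
Median log2 fold change over the measured genes of 11 gene lists (bars), between late and early growth pulp, near resting and late growth pulp, and resting apical dermal papilla and near resting pulp. Cell cycle genes fall at the first step, keratinocyte genes rise near rest and are lower in the resting papilla, and matrix genes are lower in the resting papilla.

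Over the whole span from early growth to near rest, KRT75 had the largest rise of the named genes (log2 fold change of 12.35 ± 0.23 (SE), adjusted p = 1.5e-07) and ASIP the largest fall, from 5216 ± 1302 to 11.9 ± 6.91 TPM (log2 fold change of -8.75 ± 0.49 (SE), adjusted p = 5.8e-06). The transglutaminase TGM3 (6.77 ± 0.43), ENDOU (7.04 ± 0.43), SMOC2 (7.03 ± 0.37) and EDYM2 (6.70 ± 0.61) rose, and HEPHL1, at 98.4 ± 26.1 TPM, was listed at 0 in early growth. SST (-7.52 ± 0.51), OvoDA3 (-6.67 ± 0.35) and COL14A1 (-6.57 ± 0.29) fell, and GAL was listed at 0 near rest.

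Between these stages, of the cell cycle list 0 of 38 were higher, 37 lower and 1 not called (0 and 37 adjusted over the list alone). For cell cycle genes the median log2 fold change was -2.49 (camera adjusted p = 6.4e-10, adjusted p = 0.43 with an estimated correlation). MCM4 went from 71.6 ± 0.643 to 16.1 ± 0.536 TPM. Of the oxidative phosphorylation list, 0 of 31 were higher, 24 lower and 7 not called (0 and 24 adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of -0.53 (camera adjusted p = 0.0013, adjusted p = 0.90 with an estimated correlation). With median-of-ratios scaling the median was -0.23, with 12 lower. Among its smallest p-values were those of COX5A (-0.70 ± 0.08, and -0.40 with that scaling) and UQCRB (-1.14 ± 0.14). Of the matrix protease list, 12 of 28 were higher, 7 lower and 9 not called (12 and 7 adjusted over the list alone). For matrix protease genes the median log2 fold change was 0.57 (camera adjusted p = 0.016, adjusted p = 0.39 with an estimated correlation). MMP9 (6.59 ± 0.30) and MMP11 (3.77 ± 0.10) rose and ADAMTS2, which processes procollagen, fell (-4.48 ± 0.23). Of the immediate-early and stress list, 18 of 24 were higher, 0 lower and 6 not called (18 and 0 adjusted over the list alone). Immediate-early and stress genes had a median log2 fold change of 1.65 (camera adjusted p = 1.8e-09, adjusted p = 0.27 with an estimated correlation). DUSP1 went from 9.08 ± 0.023 to 224 ± 92.9 TPM. The limma test called 2785 genes higher and 5558 lower. With median-of-ratios scaling the median of all genes moved by 0.25 and the calls were 4284 higher and 3993 lower, against 3806 and 4535 with quantile normalization.

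The resting apical dermal papilla was compared with near resting pulp, a contrast in which stage and tissue part change together. PENK, the enkephalin precursor, was at 9968 ± 891 TPM in the papilla and 121 ± 91.3 TPM in near resting pulp (log2 fold change of 6.58 ± 0.40 (SE), adjusted p = 7.0e-06), and at 9798 ± 178 TPM in early growth pulp. SLC22A16 (5.99 ± 0.19), the orphan receptors NR4A2 (5.77 ± 0.23) and NR4A3 (5.73 ± 0.54), CNKSR2 (5.72 ± 0.18) and the opsin OPN5L2, at 668 ± 39.8 TPM (5.49 ± 0.31), were higher in the papilla. CYP1C1, a cytochrome P450 gene, was at 146 ± 32.5 TPM and listed at 0 in near resting pulp. SPON2, a secreted matrix protein gene, was at 191 ± 21.6, 196 ± 2.96 and 191 ± 17.9 TPM in early, late and near resting pulp and at 0.226 ± 0.179 TPM in the papilla (log2 fold change of -7.30 ± 0.14 (SE), adjusted p = 6.9e-08). KRT75 (-12.78 ± 0.21), EDQM3 (-11.84 ± 0.27), CLDN1 (-8.20 ± 0.38) and the fatty acid binding FABP5 (-7.00 ± 0.61) were lower too.

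Most fibrillar collagen and matrix genes were lower in the resting papilla. Of the fibrillar collagen and matrix list, 3 of 33 were higher, 26 lower and 4 not called (3 and 26 adjusted over the list alone). Fibrillar collagen and matrix genes had a median log2 fold change of -1.37 (camera adjusted p = 3.6e-10, adjusted p = 0.30 with an estimated correlation). SPARC went from 8954 ± 1054 TPM in near resting pulp to 2292 ± 43.7 TPM in the papilla, COL5A1 from 733 ± 80.7 to 130.0 ± 2.26 TPM and FBN2 from 124 ± 15.9 to 0.638 ± 0.412 TPM. Of the matrix protease list, 2 of 28 were higher, 19 lower and 7 not called (2 and 19 adjusted over the list alone). Matrix protease genes had a median log2 fold change of -1.31 (camera adjusted p = 1.4e-06, adjusted p = 0.12 with an estimated correlation). Among its smallest p-values were those of MMP11 (-2.52 ± 0.10) and MMP13 (-4.50 ± 0.19). Of the hyaluronan and proteoglycan list, 2 of 18 were higher, 12 lower and 4 not called (2 and 12 adjusted over the list alone). Hyaluronan and proteoglycan genes had a median log2 fold change of -1.02 (camera adjusted p = 2.9e-04, adjusted p = 0.12 with an estimated correlation). The glypican GPC3 went from 219 ± 10.7 to 2.53 ± 0.299 TPM. Of the ribosomal protein list, 49 of 54 were higher, 0 lower and 5 not called (49 and 0 adjusted over the list alone). For ribosomal protein genes the median log2 fold change was 0.59 (camera adjusted p = 1.4e-06, adjusted p = 0.60 with an estimated correlation). With median-of-ratios scaling the median was 0.30, with 39 higher and 3 lower. RPLP1 reached 14343 ± 1144 TPM. Of the cell cycle list, 3 of 38 were higher, 24 lower and 11 not called (3 and 24 adjusted over the list alone). Cell cycle genes had a median log2 fold change of -1.02 (camera adjusted p = 3.8e-06, adjusted p = 0.52 with an estimated correlation). The test called 6095 genes higher and 3221 lower. Median-of-ratios scaling moved the median of all genes by -0.25 and gave 4418 and 4555, and quantile normalization gave 5256 and 3957.

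Against early growth pulp, the resting apical dermal papilla had 4791 genes higher and 5004 lower. STC1 (log2 fold change of 9.16 ± 0.44 (SE), adjusted p = 1.5e-06), OPN5L2 (9.09 ± 0.31), FOS (9.04 ± 0.17), CWH43 (7.98 ± 0.14), GDF7 (7.96 ± 0.41), SMOC2 (7.87 ± 0.34) and the prostaglandin receptor PTGER4 (7.33 ± 0.57) were higher. ASIP (log2 fold change of -9.94 ± 0.45 (SE), adjusted p = 1.1e-06), ISLR2 (-8.57 ± 0.50), CORIN (-7.71 ± 0.30), SST (-7.61 ± 0.46), the dipeptidase DPEP1 (-7.49 ± 0.16) and COL14A1 (-7.46 ± 0.27) were lower. In the cell cycle list, 0 of 38 were higher, 37 lower and 1 not called (0 and 37 adjusted over the list alone). For cell cycle genes the median log2 fold change was -3.69 (camera adjusted p = 9.1e-13, adjusted p = 0.46 with an estimated correlation). Of the immediate-early and stress list, 22 of 24 were higher, 0 lower and 2 not called (22 and 0 adjusted over the list alone). For immediate-early and stress genes the median log2 fold change was 2.52 (camera adjusted p = 3.0e-09, adjusted p = 0.40 with an estimated correlation). Stage, tissue part and stress during handling cannot be told apart in this contrast. Of the ribosomal protein list, 40 of 54 were higher, 0 lower and 14 not called (40 and 0 adjusted over the list alone). Ribosomal protein genes had a median log2 fold change of 0.50 (camera adjusted p = 3.8e-06, adjusted p = 0.79 with an estimated correlation). Of the fibrillar collagen and matrix list, 3 of 33 were higher, 24 lower and 6 not called (3 and 24 adjusted over the list alone). For fibrillar collagen and matrix genes the median log2 fold change was -1.48 (camera adjusted p = 2.2e-05, adjusted p = 0.49 with an estimated correlation).

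Genes that set the dermal papilla apart from the pulp in experiment 1 were then followed in experiment 2, as the 200 genes with the largest called increase in papilla over pulp and the 200 with the largest called decrease among genes tested in both experiments, which leaves out WFIKKN2. From early growth to near rest, 158 of the 200 pulp genes fell, 16 rose and 26 were not called, with a median log2 fold change of -2.63 (camera adjusted p = 8.5e-15, adjusted p = 0.010 with an estimated correlation). With sets chosen without dermal papilla replicate 3, 145 fell and 34 rose. The median was -4.16 with a pseudocount of 0.1 and -4.17 with 50 genes per set, of which 41 fell and 5 rose. Of the 200 papilla genes, 79 rose, 41 fell and 80 were not called, with a median of 0.42 (camera adjusted p = 1.0e-07, adjusted p = 0.010 with an estimated correlation). Their median was 0.14 with 50 genes per set, of which 17 rose and 10 fell, 0.63 after quantile normalization and 0.77 with a pseudocount of 0.1. In the resting apical dermal papilla against near resting pulp, 80 pulp genes were lower, 39 higher and 81 not called, with a median of -0.40 (camera adjusted p = 3.9e-07, adjusted p = 0.052 with an estimated correlation). Without early growth replicate 1 or replicate 2 that median was -0.68, and with 50 genes per set it was -0.70. Of the papilla genes, 87 were higher, 47 lower and 66 not called in that contrast. Their median of 0.44 was above 0 while the camera test pointed down, with an adjusted p of 0.95 and an adjusted p = 0.96 with an estimated correlation, so the set was not called. With median-of-ratios scaling their median was 0.22, 72 were higher and 56 lower, and the camera test pointed up with an adjusted p of 0.43.

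Markers of other cell types were followed in every group. The hemoglobin gene HBBA was at 368 ± 43.6 TPM in dermal papilla, 1239 ± 131 TPM in sheath, 588 ± 289.7 TPM in peripheral pulp and 649 ± 132 TPM in central pulp. In experiment 2 it was at 366 ± 87.7 TPM in early growth pulp, 317 ± 18.9 TPM in late growth, 114 ± 71.9 TPM near rest and 1106 ± 382 TPM in the resting papilla. The leukocyte gene PTPRC was at 0.775 ± 0.466, 3.11 ± 0.827, 12.0 ± 4.29 and 30.2 ± 6.37 TPM in the dermal papilla, sheath, peripheral and central pulp, and at 12.6 ± 0.282, 7.24 ± 1.48, 12.2 ± 1.98 and 23.3 ± 1.19 TPM in early, late and near resting pulp and the resting papilla. In the resting papilla against near resting pulp, 8 leukocyte list genes were higher and 10 lower, with a median log2 fold change of -0.13. PTPRC therefore does not stand for the leukocyte list in that contrast. KRT5 was at 173 ± 86.0 TPM in peripheral and 16.2 ± 11.3 TPM in central pulp, and at 519 ± 81.7 TPM in early growth, 98.2 ± 2.34 TPM in late growth, 1337 ± 1317 TPM in near resting pulp and 86.6 ± 22.4 TPM in the resting papilla. PECAM1 was not matched to a gene name and is not used here.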

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

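Leaving out peripheral pulp replicate 1 and central pulp replicate 3 together was chosen after seeing the data, and gave 6571 calls for peripheral pulp, 5870 for central pulp and 2717 between them. Counts of called genes stayed within 1.5 times under every alternative run, except for near resting against late growth pulp, where leaving out 1 library gave 2782 to 5459 calls (2782 without late growth replicate 1, 2913 without replicate 2) and a fit on only its 2 groups gave 1980, which has fewer libraries to estimate the spread. Fewer libraries alone do not account for the 1980. Fitting only 2 groups raised late against early growth from 7946 to 8153 calls and resting papilla against early growth from 9795 to 10781. Counts with near resting pulp fell, from 8343 to 5928 against early growth and 9316 to 8777 against the resting papilla. Of experiment 2, the 2 near resting libraries differed most (SD of log2 difference 0.64, other pairs 0.32 to 0.45). A spread shared by all groups may therefore raise these counts. A library left alone in its group was assumed to vary like the other groups. With the estimated correlation 0 of 136 gene list calls passed, and the lowest adjusted p was 0.0573. Pulp genes in the resting papilla against near resting pulp had the same median, -0.40, with an adjusted p of 0.0523. In both, the only setting changed was that for the correlation between the genes of a list. With an estimated correlation, camera also uses the residual degrees of freedom, 8 and 5 here. The lost calls therefore cannot be put down to correlation alone. Of the 136 list calls, 11 were lost with a filter at 5 TPM, 12 with median-of-ratios scaling, 17 with quantile normalization, 5 without trend and robust settings, 4 with a pseudocount of 0.1 and 0 without a filter. Leaving out 1 library ended 0 to 8 of the 89 list calls of experiment 1, with 8 without peripheral pulp replicate 1 and 5 without dermal sheath replicate 1, and 1 to 6 of the 47 of experiment 2, with 6 without near resting replicate 1. Of 649 gene-by-contrast results for named genes, none reversed. Most of these genes were chosen for large changes or small p-values in these same libraries, which makes a reversal unlikely. Median-of-ratios scaling ended 6 calls, quantile normalization and a pseudocount of 0.1 each 2 and no filter 1, a pseudocount of 0.1 and quantile normalization each added 1, and a filter at 5 TPM or a fit without trend and robust settings changed 0. A pseudocount of 0.1 widened 9 printed log2 fold changes by over 1.5 times: NEFL in sheath to 3.96, MRC1 in peripheral pulp to -5.39, CHRDL1 in central pulp to -8.23, CRYBB2 and DKK1 in papilla against sheath to 7.60 and 6.82, HAPLN1 and AvBD1 in peripheral against central pulp to 7.48 and -8.13, LAMA1 in late against early growth to 4.81 and NTRK3 near rest against late growth to -6.94. For named genes, leaving out 1 library ended 0 to 3 calls and added at most 1, for genes whose fold in that contrast is not printed. Deviations of same-numbered libraries correlated between -0.0846 and 0.143 over 18 pairs in experiment 1, against -0.118 to 0.111 for other pairs. In experiment 2 they correlated between -0.0403 and 0.113 over 12 pairs, against -0.113 to 0.0403 for other pairs. Each experiment had 1 same-numbered pair over 0.1. The 12 pairs are not separate checks, because the deviations of 2 libraries in a group mirror each other. These low values cannot settle whether replicate numbers pair the samples. With the replicate number as a block, the counts were 10524 (parts), 7351, 7728, 7443 and 6816 (papilla, sheath, peripheral and central pulp against the rest), 5284, 8167 and 3522 (papilla against sheath, papilla against pulp, peripheral against central pulp), 11488 (stages) and 6871, 3344, 7405, 7871 and 8640 (late against early growth, near rest against late and early growth, resting papilla against near rest and early growth). The block ended 2 list calls. Depth is unknown for TPM, so what it limits could not be measured.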

Other observations

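Tests of scaling, of epidermis taken at dissection and of leukocytes of all kinds were chosen after the result was seen, while the gene sets for epithelium, heat shock and granulocytes were written down before their values were read. Of the basement membrane list, 8 of 13 were higher, 2 lower and 3 not called (9 and 2 adjusted over the list alone) in late against early growth pulp. Basement membrane genes had a median log2 fold change of 0.56 (camera adjusted p = 0.0021, adjusted p = 0.27 with an estimated correlation). The matricellular gene SMOC1 rose (3.00 ± 0.08, SE) with the laminin LAMA1 (2.62 ± 0.22) and perlecan, HSPG2 (1.12 ± 0.10). In peripheral pulp against the other 3 parts, 2 of 12 were higher, 9 lower and 1 not called (2 and 9 adjusted over the list alone). For basement membrane genes the median log2 fold change was -0.92 (camera adjusted p = 0.0018, adjusted p = 0.40 with an estimated correlation). The linker protein nidogen-1 (NID1, 1.36 ± 0.08) ran against AGRN (-1.58 ± 0.13) and COL4A1 (-1.04 ± 0.10).

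Of the adipocyte list, 10 of 18 were higher, 0 lower and 8 not called (10 and 0 adjusted over the list alone) near rest against early growth. Adipocyte genes had a median log2 fold change of 0.56 (camera adjusted p = 7.4e-04, adjusted p = 0.27 with an estimated correlation). Of all genes tested, 55.9% were called in that contrast. Without near resting replicate 1 the median was 0.31, with 7 higher and 1 lower. LPL, which releases fatty acids from lipoproteins, rose from 86.8 ± 1.80 to 149.9 ± 9.24 TPM, the leptin receptor LEPR from 0.717 ± 0.286 to 8.11 ± 3.58 TPM and FABP4 from 0.422 ± 0.596 to 11.7 ± 3.38 TPM. Of the angiogenic factor list, 0 of 20 were higher, 11 lower and 9 not called (0 and 12 adjusted over the list alone) near rest against late growth. Angiogenic factor genes had a median log2 fold change of -0.54 (camera adjusted p = 0.014, adjusted p = 0.31 with an estimated correlation). Without late growth replicate 1, 6 were lower, and 6 with either scaling. NRP2 fell from 186 ± 0.448 to 95.5 ± 5.10 TPM and THBS1 from 393 ± 3.80 to 124 ± 10.7 TPM.

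Most keratinocyte list genes rose in near resting pulp. Scaling is argued against as the whole cause, since with median-of-ratios scaling the keratinocyte list still had a median log2 fold change of 3.91 near rest against late growth. Epithelial genes outside that list also rose, 11 of 14 with a median of 2.84, and the most abundant of them, PPL and KLF5, were at 221 ± 96.8 and 151 ± 94.2 TPM (SD, n = 2), so epithelial cells in these libraries are a candidate source. Late growth pulp already had 12 of those 14 genes and 19 of 25 keratinocyte list genes at 1 TPM or more. In 18 of the 23 tested list genes both near resting libraries lay above both late growth libraries, so a stage change and the amount of epidermis taken at dissection cannot be told apart with 2 libraries per stage.

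Of the immediate-early and stress list, 23 of 24 genes rose in late growth pulp. With median-of-ratios scaling the list had a median log2 fold change of 2.99, which argues against scaling as the whole cause. Heat-shock genes outside the list had a median of 0.68 in late against early growth, 9 of 14 higher and 2 lower, with BAG3 at 43.1 ± 5.42 TPM early and 674 ± 20.8 TPM late. Stress during handling and a stage change cannot be told apart here, because all libraries of a stage may have been handled alike, and a change of the stage itself stays untested.

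Antimicrobial granule genes were higher in central than in peripheral pulp. The median log2 fold change of the leukocyte list, peripheral minus central, was -0.50 (SD over genes 0.386) against -5.81 for 8 granule genes. Of the 22 leukocyte list genes, 13 were higher in central pulp and 0 lower. The 8 granule genes were picked for their large change in these same libraries. Their larger median therefore cannot decide whether leukocytes of all kinds rose alike. Of 9 granulocyte genes outside those 8, 6 were higher in central pulp and 1, G0S2, was lower there, with a median of -1.91, so granulocytes in the central pulp libraries are a candidate source. AvBD2 was at 115 ± 30.8 TPM and LECT2 at 211 ± 53.2 TPM, peripheral pulp had 0 of the 8 and 5 of the 9 genes at 1 TPM or more, and AvBD2 was listed at 0 in all 9 libraries of experiment 2. Whether the cells lay in vessels or in the pulp stays untested.

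Chance division of the libraries of experiment 1 was tested with 100 splits into 4 groups of 3, the real one included. For each of 6 results only the real split, 1 of 100, gave as many genes, which argues against a random division of these 12 libraries. The other splits mix different parts in a group, so they cannot show which part differs. They also cannot show whether other birds or dissections would give the same differences. The F test called 10532 genes against at most 3244 in another split. Counts against the other 3 parts were 7333 for dermal papilla (highest other 3342), 7659 for sheath (3237), 7391 for peripheral pulp (3277) and 6760 for central pulp (3084), and papilla against pulp gave 8109 (3999). For papilla against sheath (5203, highest other 3) and peripheral against central pulp (3472, highest other 2), the 10 possible splits are too few for a share under 0.05.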
